A study of Homo sapiens with 4 samples.

How the data were processed

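RNA was taken from MCF-7 breast cancer cells in which MBNL2 had been silenced with an siRNA or which had received a non-silencing siRNA. Per the labels' protocols, 200000 cells per well of a 12-well plate received 200 pmol of siRNA by lipid transfection at seeding, and were moved 24 h after seeding from 21% to 0.5% oxygen (37 °C, 5% CO2) for 48 h. Total RNA was DNase-treated, and poly(A)-enriched strand-specific libraries were made with a TruSeq kit and run on a NextSeq 500, per the labels' protocols. Groups and replicate numbers were taken from the labels, which give 2 libraries per group.

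The values are counts: the files the authors deposited hold whole numbers of reads per Ensembl gene, 1 file per library, with no normalization. FastQC 0.11.5, STAR 2.4.5a and HTSeq 0.6.1 and the builds hg38 and GRCh38 are named in the submitters' processing notes, with no roles or order. The annotation release, the strand setting of the counter and the rule for reads that map to several places are not given in the sources used here. Such settings can move reads between a gene and its overlapping, antisense or near-identical partners, so named genes are given with the share of their exon bases that other annotated genes overlap where that share is large. Deposited counts sum to 62393699, 59218194, 57381875 and 68965140 in siCTRL replicates 1 and 2 and siMBNL2 replicates 1 and 2. HTSeq's own summary lines were kept out of library sizes and tests. Reads without a feature were 15.3%, 20%, 15.9% and 14.7% of the total in the same order, and ambiguous reads were between 2.18% and 2.22%. Mitochondrially encoded genes were not analysed here.

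The files hold 50419 genes, of which 49841 matched GENCODE 29 by Ensembl identifier without version. Coordinates, gene types and transcripts are from GENCODE 29 on GRCh38, while the authors' own release is not known, and 578 identifiers without a match were tested without coordinates. The siRNA site was found by exact search in MBNL transcripts.

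The 4 libraries were fitted together with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10 and a minimum total of 15, TMM factors of 0.946, 0.82, 1.172 and 1.1, quasi-likelihood F-test, two-sided, Benjamini-Hochberg adjustment over 17658 genes, threshold 0.05). The fit had 2 residual degrees of freedom per gene, a prior of 5.05 and a common biological coefficient of variation of 0.168. Adjusted p-values of single genes are from this edgeR test unless another tool is named. CPM values are normalised with the TMM factors, and log2 fold changes are siMBNL2 minus siCTRL. Standard errors (SE) were derived from the F-test, as the absolute log2 fold change divided by the square root of F, and intervals from the model use them. The ratio interval for a gene with few control reads is an exact binomial one that covers counting error only. Replicates were compared before averaging: the chi-square per degree of freedom over genes was 95.8 for the siCTRL pair and 21.1 for the siMBNL2 pair, far above sampling noise, so all 4 were kept as separate libraries.

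On simulated data with known changes for the comparison of siMBNL2 against siCTRL (17279 genes), the same steps recovered 72% of 2-fold rises, 70% of 2-fold falls, 100% of 4-fold rises and 96% of 4-fold falls, and called 8 of 17079 unchanged genes. The list test found the 1 list that had been lowered and 0 of 20 random lists among 17658 genes. The simulation drew genes independently, with the same dispersion for a gene in all 4 libraries and no displaced control library. It therefore checks the code, and does not show how often calls are false in these data, where the siCTRL pair varied more.

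Gene lists, alternatives and the rule for named genes were set before the data were examined. The rule takes MBNL2, MBNL1 and MBNL3, the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those called, with a mean of at least 5 CPM and both knockdown libraries on the same side of both controls, and up to 5 non-coding genes under the same conditions. It adds up to 4 members per list with the smallest p (2 where fewer than 2 passed) and the hypoxia genes VEGFA, CA9, HIF1A, EPAS1, SLC2A1 and NDRG1. GAPDH and other members that complete a list's small count (TM7SF2, PMVK and IRF1) were named after their values were seen. Lists were tested with limma 3.58.1 (camera with a preset correlation of 0.01, adjusted over 25 lists), again with an estimated correlation, and with fry. With an estimated correlation, camera is limited to the 2 residual degrees of freedom, so it has little power here and a lost call does not decide the question. A list's median was also set against 10000 random lists of protein-coding genes matched on mean expression. Those lists draw genes independently and do not carry the correlation between members of a real list.

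The alternatives were RLE factors, upper-quartile scaling, library totals, 2 other filters on low counts (none, and at least 1 CPM in 2 libraries), DESeq2 1.42.0, limma-voom, the replicate number as a block, a threshold of 0.01 and leaving out each library. A fit with cyclic loess normalization was added after the data had been seen. For motif tests, the longest annotated 3' UTR regions of at least 50 bases were searched with Python 3.11.15 and numpy 2.4.6, covering 13141 genes, 98.5% of the protein-coding genes tested.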

Results

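RNA abundance was measured by poly(A)-selected, strand-specific sequencing in MCF-7 cells, an established luminal, estrogen receptor-positive breast cancer line. The cells carried a small interfering RNA (siRNA) against MBNL2 or a non-silencing control siRNA, and both groups were kept at 0.5% oxygen for 48 h. Each group held 2 libraries, siCTRL replicates 1 and 2 and siMBNL2 replicates 1 and 2. Reads assigned to genes came to 62393699 and 59218194 in the siCTRL libraries and 57381875 and 68965140 in the siMBNL2 libraries. The labels did not say whether the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The series holds a single comparison, MBNL2 siRNA against control siRNA in hypoxia. It asks how transcript abundance in hypoxic cells differs when MBNL2, a member of the muscleblind family of splicing and RNA-stability regulators, is depleted.

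MBNL2 itself (ENSG00000139793.18; GRCh38 chromosome 13, 97221434 to 97394120, plus strand) was the first transcript examined. Its normalised abundance was 98.62 and 95.56 CPM (counts scaled to library size) in the siCTRL libraries and 10.04 and 10.31 CPM in the siMBNL2 libraries, from 5821, 4637, 675 and 782 reads. The log2 fold change was -3.25 (SE 0.14; edgeR adjusted p = 0.00114, n = 2 per group), so that 10.5% of the control level remained (9.5 to 11.6 at 1 SE on either side). MBNL2 had the smallest p of all 17658 genes tested. The siRNA sense strand, CACCGTAACCGTTTGTATG as DNA, matched the genome at chromosome 13, 97346902 to 97346920 on the plus strand. That site lies in coding sequence of exon 5 and is present in 4 of the 5 protein-coding MBNL2 transcripts of GENCODE 29. The closest stretch in any MBNL1 transcript had 4 mismatches to it, and the closest in any MBNL3 transcript had 6.

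The paralogs did not pass the test. MBNL1 stood at 91.4 ± 2.55 CPM with control siRNA and 95.7 ± 2.72 CPM with MBNL2 siRNA (SD, n = 2), a log2 difference of 0.07 (SE 0.13; edgeR adjusted p = 0.707). MBNL3 stood at 24 and 23.4 CPM (log2 difference -0.03, SE 0.16; edgeR adjusted p = 0.891), and its sign was positive under upper-quartile scaling, library totals, cyclic loess and the CPM filter (at least 1 CPM in 2 libraries), and without siCTRL replicate 1. Part of the MBNL1 exons (15.6% of bases) overlapped genes on the other strand. The strand setting of the counting is not given in the sources used here.

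**Figure D1:**
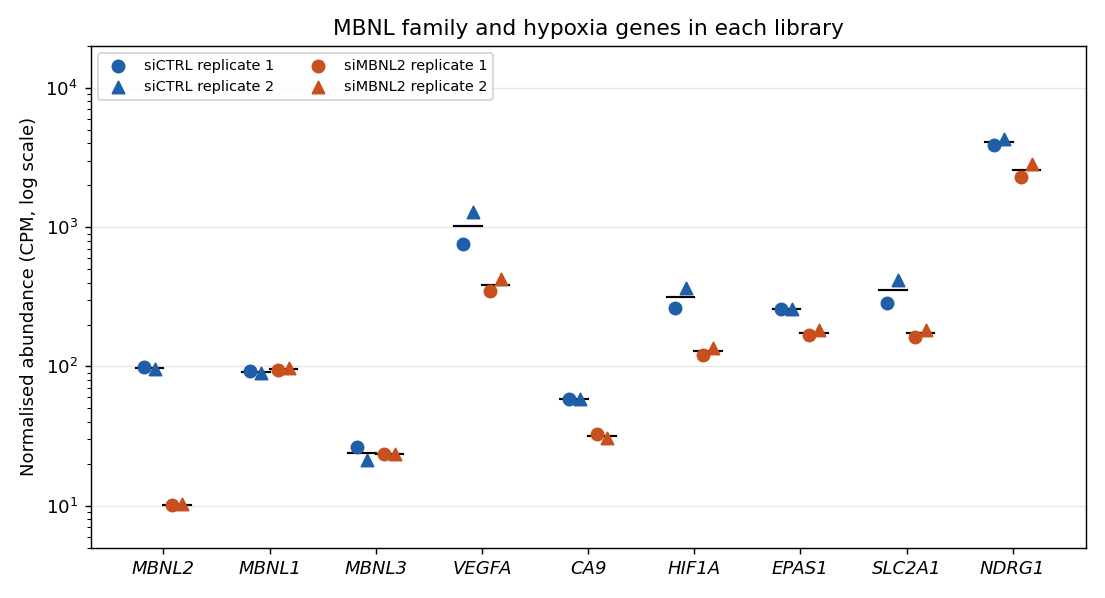
Normalised abundance (CPM, log axis) of the 3 MBNL genes and 6 hypoxia genes in each of the 4 libraries, with circles for replicate 1, triangles for replicate 2 and black lines for group means. MBNL2 falls from 97.1 to 10.2 CPM between the group means while all 4 libraries lie between 89.63 and 97.62 CPM for MBNL1 and between 21.37 and 26.55 CPM for MBNL3, and each of the 6 hypoxia genes is lower in both siMBNL2 libraries than in both siCTRL libraries.

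Across the transcriptome, 2657 genes rose and 2425 fell at an edgeR adjusted p under 0.05, together 28.8% of those tested. A change of at least 2-fold was found for 1906 of the genes that rose and 728 of those that fell. Among 13345 protein-coding genes, 1758 rose and 2175 fell. That balance turned with the scaling: 2369 rose and 1256 fell under upper-quartile scaling, and 2808 and 616 under library totals. The protein-coding genes with the largest rises were LGR6 (log2 fold change 3.01), ITGB8 (2.84), IGFBP5 (2.71), SULF1 (2.68), ZNF594 (2.63), SAMD9 (2.58), COL5A2 (from 2.30 to 13.1 CPM), HSPA6 (2.37), AMPD3 (2.34) and METAP1D (2.32). LGR6 is a receptor for R-spondins, ITGB8 an integrin subunit and COL5A2 a fibrillar collagen chain. IGFBP5, an insulin-like growth factor-binding protein, was the most abundant of them and went from 105 to 689 CPM (SE of the log2 fold change 0.39; edgeR adjusted p = 0.0162). The largest falls besides MBNL2 were those of ANKRD37 (-3.46), AC013394.1 (-3.06), EDN2 (-2.80), CYP1A1 (-2.64), ISM2 (-2.58), EIF4A1 (-2.43), PER1 (-2.42), NDUFV2 (-2.31) and MXD1 (-2.30). EDN2, which encodes the vasoconstrictor peptide endothelin 2, went from 56.9 to 8.18 CPM (SE 0.20; edgeR adjusted p = 0.0105). ISM2 had the same adjusted p, the smallest after that of MBNL2. Several of the genes with the largest changes differed widely between siCTRL replicates 1 and 2. CPM values were 54.5 and 202 for ANKRD37, 5.01 and 27 for AC013394.1, and 114 and 285 for CYP1A1. They were 20.35 and 103 for EIF4A1 and 279 and 685 for PER1. Among the rises, they were 5.59 and 1.09 for ZNF594 and 3.41 and 0.54 for SAMD9. EDN2 (50.1 and 63.6) and ISM2 (28.5 and 33.1) differed less. AC013394.1, EIF4A1 and NDUFV2 share 41.2%, 48.6% and 28.4% of their exon bases with other genes on their own strand, and ANKRD37 shares 35.2% with a gene on the other strand, so their counts are uncertain. The calls of EIF4A1 and AC013394.1 were lost with limma-voom and cyclic loess, that of EIF4A1 also with library totals, and those of EIF4A1 and SAMD9 with DESeq2. The largest non-coding changes were rises of ENSG00000280128 (2.96), LINC00342 (2.77), ENSG00000260337 (2.68), HERPUD2-AS1 (from 2.15 to 11.5 CPM) and CALML3-AS1 (from 2.18 to 11.5 CPM).

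The balance of rises and falls depended on the scaling. Upper-quartile scaling gave 3394 higher and 1415 lower genes and library totals 3903 and 711, with the median log2 difference of all genes at 0.20 and 0.40 in place of 0.04. The 4 libraries were also unevenly spaced. The median absolute log2 difference was 0.33 between the siCTRL libraries, 0.14 between the siMBNL2 libraries and 0.35 between siCTRL replicate 1 and siMBNL2 replicate 2. GAPDH took 6.05% and 7.05% of assigned reads in the siCTRL libraries and 3.88% and 4.75% in the siMBNL2 libraries. Its log2 difference was -0.98 (SE 0.33), and it passed with library totals or either siCTRL library left out, but not in the main test (edgeR adjusted p = 0.0626). Without siMBNL2 replicate 1 the counts were 672 higher and 462 lower, and without siMBNL2 replicate 2 they were 1432 and 984. Without siCTRL replicate 1 they were 5985 and 5507, and without siCTRL replicate 2 they were 3801 and 3701. At an adjusted p under 0.01, MBNL2 was the only gene called (0 higher, 1 lower by edgeR, against 8157 genes at an unadjusted p under 0.05).

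**Figure D2:**
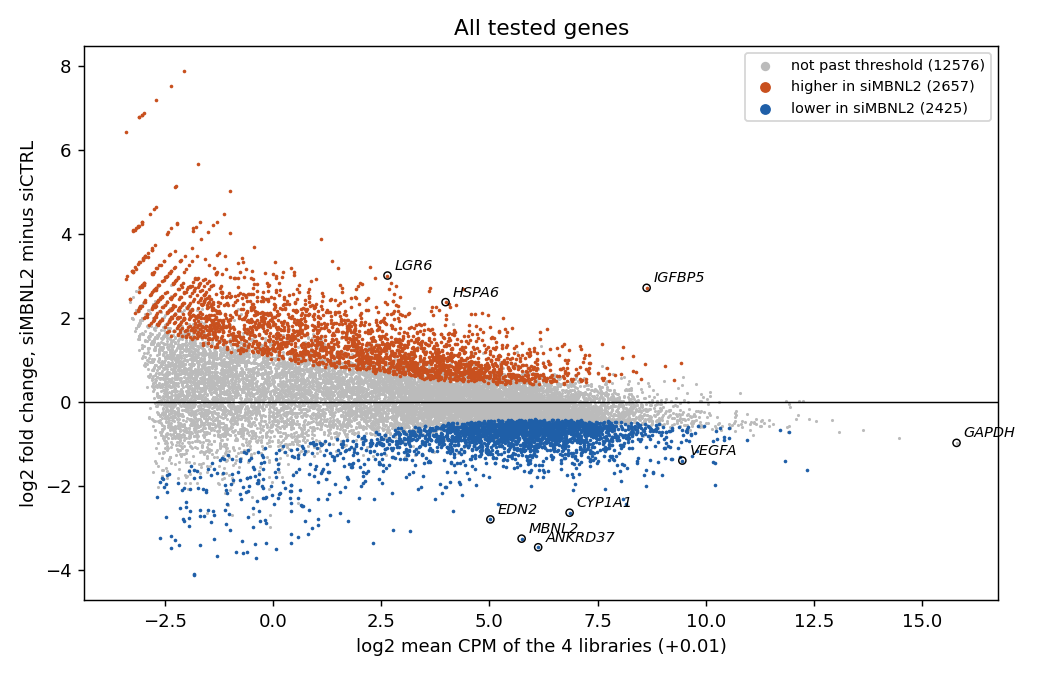
Log2 fold change (siMBNL2 minus siCTRL) against log2 mean CPM of the 4 libraries for the 17658 tested genes, with the 2657 higher genes in orange, the 2425 lower genes in blue and 9 named genes circled. The Spearman correlation of fold change with mean expression across genes, which are not independent replicates, was -0.42.

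Many genes of the hypoxia response were lower with MBNL2 siRNA. VEGFA, the angiogenic growth factor, went from 1018 ± 370 to 387 ± 51.3 CPM (SD, n = 2), a log2 fold change of -1.40 (SE 0.27; edgeR adjusted p = 0.0193). The transcripts of the hypoxia-inducible transcription factor subunits HIF1A and EPAS1 changed by -1.28 (SE 0.19; edgeR adjusted p = 0.0166) and -0.56 (SE 0.14; 0.0294). The glucose transporter SLC2A1 (-1.03), the carbonic anhydrase CA9 (-0.89) and NDRG1 (-0.68) fell as well. CA9 shares 38.5% of its exon bases with a gene on the other strand. Of 43 measured HIF target genes, 30 fell, 0 rose and 13 were not called (36 lower and 0 higher adjusted over the list alone). The median log2 fold change was -0.85 (camera adjusted p = 2.41e-15; adjusted p = 0.669 with an estimated correlation). LOX, a collagen cross-linking oxidase, fell by 1.65 on the log2 scale, the carbonic anhydrase CA12 by 1.22 and the glucose transporter SLC2A3 by 1.94. The median of the same list differed by 0.25 between siCTRL replicate 2 and siCTRL replicate 1, the opposite way to the knockdown. In the list of the HIF pathway and oxygen sensing, 1 of 16 genes rose (ARNT2, 1.67) and 6 fell, among them RBX1 (-0.87), with 1 and 6 adjusted over the list alone. Its median was -0.41 (camera adjusted p = 0.032; adjusted p = 0.669 with an estimated correlation), inside the -0.51 to 0.01 of expression-matched random lists, and -0.01 between the siCTRL libraries. Under upper-quartile scaling, library totals and cyclic loess, the HIF target count was 24, 22 and 21 lower (medians -0.68, -0.47 and -0.43), and the HIF pathway count was 2, 1 and 2 lower (medians -0.24, -0.04 and -0.06). The HIF target count was 10 lower without siMBNL2 replicate 1 and 20 without siMBNL2 replicate 2, the HIF pathway count was 1 lower in both cases, and the HIF pathway list lost its camera call without siMBNL2 replicate 1, siMBNL2 replicate 2 or siCTRL replicate 1, and under the CPM filter. EPAS1 and NDRG1 were not called under upper-quartile scaling, library totals or cyclic loess, nor with either siMBNL2 library left out. RBX1 was not called with library totals or with either siMBNL2 library left out, CA9 with library totals or without siMBNL2 replicate 2, and SLC2A1 without siMBNL2 replicate 1.

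The glycolysis and angiogenesis lists share members with the HIF targets, such as ALDOC and VEGFA. Of 21 glycolysis genes, 11 fell and 0 rose (15 and 0 adjusted over the list alone), with ENO2 at -1.43, ALDOC at -1.32 and PFKFB4 at -0.83. The median was -0.72 (camera adjusted p = 3.43e-06; adjusted p = 0.669 with an estimated correlation), and 0.26 between the siCTRL libraries. Of 22 angiogenic factors, 9 fell and 2 rose (11 and 3 adjusted over the list alone), with a median of -0.60 (camera adjusted p = 0.00501; adjusted p = 0.669 with an estimated correlation), and 0.37 between the siCTRL libraries. The Notch ligand JAG1 fell by 1.62 on the log2 scale and ANGPTL4 fell by 1.16, while the receptor NRP2 rose from 0.06 to 0.41 CPM. Library totals gave 1 higher and 8 lower glycolysis genes (median -0.35) and 3 higher and 4 lower angiogenic factors (-0.23), and cyclic loess gave 2 and 6 (-0.13) and 1 and 5 (-0.58). Without siCTRL replicate 1, 5 angiogenic factors rose and 13 fell. Without siMBNL2 replicate 1 the lower counts were 2 for glycolysis and 3 for angiogenic factors, and without siMBNL2 replicate 2 they were 5 and 7. PFKFB4 and NRP2 were not called with either siMBNL2 library left out, nor was NRP2 under cyclic loess.

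Most of the listed mitotic genes fell. Of 34 measured members, 26 fell, 0 rose and 8 were not called (28 lower and 1 higher adjusted over the list alone). The median was -0.84 (camera adjusted p = 2.41e-15; adjusted p = 0.669 with an estimated correlation), and 0.11 between the siCTRL libraries. DLGAP5, a spindle protein, changed by -1.31 (SE 0.16), CCNA2, which encodes cyclin A2, by -1.14, the kinase PBK by -1.25 and the checkpoint kinase BUB1 by -1.27, all at an edgeR adjusted p of 0.0162. Genes of DNA replication did not pass camera: 2 of 42 rose (MCM3, 0.87, and DHFR, 0.95), 2 fell (ORC1, -0.98, and ORC6, -0.82), and 0 and 1 passed when adjusted over the list alone. Their median was -0.09 (camera adjusted p = 0.491), positive under upper-quartile scaling and library totals, and 0.01 between the siCTRL libraries. Among 26 replication-dependent histone genes, H4C8 rose (1.28) and 4 fell, including H2BC21 (-1.88) and H1-2 (-1.58), with 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.311). The histone median was -0.47, but it differed by 1.16 between siCTRL replicate 2 and replicate 1 and was 0.31 without siCTRL replicate 2. In siCTRL replicates 1 and 2, H2BC21 stood at 167 and 667 CPM and H1-2 at 91.8 and 294 CPM. Histone genes are near-identical copies, so their counts are uncertain. How well poly(A) selection captured their transcripts in each library was not tested. The mitosis count was 17 lower under library totals (median -0.47), where DNA replication had 4 higher and 0 lower genes and histones 5 and 0. The mitosis count was 11 lower without siMBNL2 replicate 1 and 17 lower without siMBNL2 replicate 2. For DNA replication the counts were 8 higher and 12 lower without siCTRL replicate 1 and 7 and 5 without siCTRL replicate 2, and for histones they were 3 and 18, and 10 and 5. The calls of MCM3, DHFR, ORC1 and ORC6 were lost without siMBNL2 replicate 1, and those of H2BC21 and H1-2 with DESeq2, limma-voom and every scaling except RLE. With either siMBNL2 library or siCTRL replicate 1 left out, the histone list passed camera.

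Of 24 cholesterol synthesis genes, 17 fell and 2 rose, TM7SF2 and PMVK (19 and 2 adjusted over the list alone). The median was -0.80 (camera adjusted p = 7.39e-09; adjusted p = 0.669 with an estimated correlation), and 0.38 between the siCTRL libraries. HMGCR, the rate-limiting enzyme of the pathway, changed by -1.36 (SE 0.17), the sterol carrier STARD4 by -1.50 and MSMO1 by -1.71. Of 44 nuclear-encoded oxidative phosphorylation genes, 24 fell and 0 rose (30 and 1 adjusted over the list alone), with a median of -0.57 (camera adjusted p = 6.4e-08; adjusted p = 0.669 with an estimated correlation), and 0.33 between the siCTRL libraries. ATP5MC3 fell by 0.94 on the log2 scale, NDUFB8 by 1.22 and COX8A by 1.16, and the last pair share 33.8% and 34.5% of their exon bases with other genes on their strand. Without siMBNL2 replicate 1, the counts were 7 lower for cholesterol synthesis and 4 lower for oxidative phosphorylation, and without siMBNL2 replicate 2 they were 10 and 11. Under library totals 5 oxidative phosphorylation genes rose and 7 fell (median -0.20), and under cyclic loess 1 rose and 8 fell (-0.33). For cholesterol synthesis, 10 and 12 genes fell under these scalings (medians -0.43 and -0.45). NDUFB8 and COX8A were not called without siMBNL2 replicate 1.

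Of 53 cytosolic ribosomal protein genes, 9 fell and 0 rose, against 45 lower and 0 higher adjusted over the list alone. RPS15 (-0.66), RPS16 (-0.72), RPS28 (-0.63) and RPL27 (-0.64) were among those that fell. The median was -0.54 (camera adjusted p = 9.5e-10; adjusted p = 0.669 with an estimated correlation), and 0.35 between the siCTRL libraries. The lower count was 0 under upper-quartile scaling, library totals and cyclic loess, and with either siMBNL2 library left out. It was 51 without siCTRL replicate 1 and 24 without siCTRL replicate 2. Ribosomal protein genes have many processed pseudogenes with which reads can be shared.

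Part of the interferon-stimulated genes rose. Of 36 measured, 11 rose, 2 fell and 23 were not called (15 higher and 2 lower adjusted over the list alone). The median log2 fold change was 1.15 (camera adjusted p = 0.000142; adjusted p = 0.669 with an estimated correlation). In siCTRL replicate 2 the median was -0.69 relative to siCTRL replicate 1. Abundance was low: OAS2 went from 0.26 to 2.04 CPM (log2 fold change 2.98, SE 0.52) and MX1 from 0.62 to 2.26 CPM (1.85). XAF1 had 1 read in the siCTRL libraries together and 81 in the siMBNL2 libraries, a normalised ratio of 60.9 with a 95% counting interval of 10.6 to 2430, and 38.3% of its exon bases overlap a gene on the other strand. The nuclease gene ISG20 fell by 1.15 on the log2 scale, and IRF1 was the other member that fell. The median was 0.71 without siCTRL replicate 2. The count that rose was 27 without siCTRL replicate 1, 19 without siCTRL replicate 2, and 12 and 14 without siMBNL2 replicates 1 and 2, and MX1 was not called without siMBNL2 replicate 1.

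Splicing regulators, p53 targets and autophagy genes passed camera, but their medians lay inside those of expression-matched random lists (-0.46 to -0.12, -0.39 to 0.06 and -0.43 to -0.06). Of 36 splicing regulators, 9 fell and 1 rose (the same counts adjusted over the list alone), with CLK1 at -1.21, HNRNPL at -1.15, RBFOX2 at -0.54 and QKI at -0.55. Their median was -0.37 (camera adjusted p = 0.00737; adjusted p = 0.669 with an estimated correlation) but 0.02 under library totals and 0.01 under cyclic loess, and it was 0.33 between the siCTRL libraries. With library totals 5 splicing regulators rose and 2 fell, and with cyclic loess 2 rose and 0 fell. All 4 named regulators lost their calls under cyclic loess. Of 28 p53 targets, 10 fell and 4 rose (10 and 4 adjusted over the list alone). GDF15 fell by 1.58 on the log2 scale, whereas SPATA18 (1.38), XPC (0.78) and BTG2 (0.60) rose. The p53 median was -0.34 (camera adjusted p = 0.0418; adjusted p = 0.669 with an estimated correlation) but 0.04 under library totals (4 higher, 1 lower), and 0.31 between the siCTRL libraries; the call was lost without siCTRL replicate 2. Of 34 autophagy and lysosome genes, 6 fell, including the cholesterol transporter NPC1 (-1.27) and ATG16L1 (-0.83), and GBA1 rose (0.68), with the same counts adjusted over the list alone. The median was -0.26 (camera adjusted p = 0.0196; adjusted p = 0.669 with an estimated correlation), 0.11 under library totals (6 higher, 3 lower), and 0.15 between the siCTRL libraries. With cyclic loess 3 p53 targets rose and 2 fell (median -0.11), and 3 autophagy genes rose and 2 fell (median 0.00). The medians without siCTRL replicate 2 were -0.16, -0.23 and -0.16. The lower counts of these lists were 3, 3 and 1 without siMBNL2 replicate 1, 4, 6 and 4 without siMBNL2 replicate 2, 20, 17 and 20 without siCTRL replicate 1, and 13, 11 and 11 without siCTRL replicate 2. RBFOX2, QKI, XPC, BTG2 and GBA1 were not called with either siMBNL2 library left out, nor ATG16L1 without replicate 1, and the p53 and autophagy lists did not pass camera under the CPM filter. XPC shares 30.4% of its exon bases with genes on the other strand.

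Several lists did not pass camera. Of 34 estrogen receptor targets, 4 rose, including MYB (1.67), and 6 fell, including STC2 (-1.46), HSPB8 (-1.57) and TFF1 (-1.29), with 4 and 6 adjusted over the list alone. Their median was -0.07 and their mean 0.01 (camera adjusted p = 0.491, direction down), and the median was positive under upper-quartile scaling, library totals and cyclic loess, and without siCTRL replicate 1. Of 36 genes of migration, adhesion and matrix, 5 rose, such as LAMB1 (2.43) and COL5A1 (1.26), and 6 fell, such as ITGA5 (-1.40) and LOXL2 (-1.03), or 5 and 7 adjusted over the list alone. Their median was 0.00 and their mean 0.10, while camera gave a downward direction (adjusted p = 0.598). Of 33 unfolded protein response and ATF4 targets, 2 rose, DDIT3 (0.90) and PHGDH (0.80), and 7 fell, including VLDLR (-0.89), or 2 and 4 adjusted over the list alone. Their median was -0.17 (camera adjusted p = 0.128), and 0.20 under library totals and 0.09 under cyclic loess. Among 23 immediate-early genes, FOS (1.29) and FOSB (1.42) rose and 6 fell, including DUSP5 (-1.19) and IER3 (-0.86), or 2 and 7 adjusted over the list alone (median -0.37, camera adjusted p = 0.174). Of 15 heat shock protein genes, 4 rose, among them HSPA6 (2.37) and DNAJA1 (0.75), and 2 fell, HSPB8 and HSPB1 (-0.87), or 5 and 2 adjusted over the list alone (median 0.12, but -0.14 without siCTRL replicate 1; camera adjusted p = 0.594). Of 13 small RNA pathway genes, AGO1 (0.76) rose, and TNRC6A (-0.58) and PRKRA (-0.55) fell, or 0 and 2 adjusted over the list alone. Their median was -0.28 (camera adjusted p = 0.292), and 0.08 under library totals. Medians between the siCTRL libraries were -0.01, -0.04, 0.12, 0.33, 0.25 and -0.21 for these lists in the order given. Under library totals the higher and lower counts were 8 and 5, 8 and 3, 4 and 1, 2 and 1, 8 and 2, and 2 and 0, and under cyclic loess 5 and 5, 5 and 3, 4 and 2, 2 and 1, 8 and 2, and 2 and 0. Upper-quartile scaling gave 3 and 3 for the unfolded protein response and 2 and 1 for immediate-early genes, whose median was -0.01 under library totals and -0.17 without siCTRL replicate 2. Without siCTRL replicate 1 the higher and lower counts of these lists were 11 and 10, 12 and 12, 4 and 13, 6 and 13, 5 and 5, and 4 and 5. Without siCTRL replicate 2 they were 7 and 9, 5 and 10, 5 and 10, 3 and 9, 7 and 3, and 2 and 8. Without siMBNL2 replicate 1 they were 1 and 4, 4 and 1, 1 and 1, 2 and 0, 1 and 1, and 0 and 0, and without siMBNL2 replicate 2 they were 3 and 5, 4 and 3, 0 and 3, 1 and 4, 2 and 1, and 0 and 0. With either siMBNL2 library left out, PHGDH, HSPB1, AGO1, TNRC6A and PRKRA were not called. Without siMBNL2 replicate 1 the same held for LOXL2, VLDLR, DUSP5, IER3 and DNAJA1, and without siMBNL2 replicate 2 for DDIT3 and FOSB. The immediate-early list passed camera without siCTRL replicate 1, the small RNA list without siCTRL replicate 2 and the unfolded protein response list without siMBNL2 replicate 2. DDIT3 and IER3 share 31.6% and 26.5% of their exon bases with genes on the other strand.

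Markers of cell identity were measured as well. Of 16 luminal epithelial markers, 6 fell and 0 rose, also when adjusted over the list alone, including KRT7 (-0.75), CLDN4 (-0.88), ELF3 (-0.82) and FOXA1 (-0.57). The luminal median was -0.42 (camera adjusted p = 0.0057; adjusted p = 0.669 with an estimated correlation) but 0.20 under cyclic loess, and 0.10 between the siCTRL libraries. Library totals gave 1 higher and 2 lower luminal markers (median -0.05) and cyclic loess 2 and 3. The median lay inside the -0.57 to -0.12 of expression-matched random lists, and 0 members fell with either siMBNL2 library left out. Of 8 basal markers, KRT17 fell (-2.29), or 3 fell and 1 rose adjusted over the list alone, and ITGB6 was at 0.46 (edgeR adjusted p = 0.0517). The basal median was -0.11 (camera adjusted p = 0.263), positive under upper-quartile scaling and library totals, and -0.01 between the siCTRL libraries. Of 4 fibroblast markers that could be tested, 3 rose, also when adjusted over the list alone: COL6A3 from 1.64 to 7.55 CPM, ACTA2 from 1.25 to 3.12 CPM and COL3A1 from 1.19 to 2.43 CPM. Their median was 1.17 (camera adjusted p = 0.0196; adjusted p = 0.669 with an estimated correlation), and -0.22 between the siCTRL libraries; the call was lost without siCTRL replicate 1, and 1 marker rose with either siMBNL2 library left out. Of 5 endothelial markers, 0 were called by edgeR over all genes or over the list alone, with EMCN at 0.55 (edgeR adjusted p = 0.15) and ESAM at -0.56 (0.235). The endothelial median was 0.25 (camera adjusted p = 0.958). It was -0.45 under cyclic loess, -0.17 without siCTRL replicate 2 and 0.83 without siCTRL replicate 1. Of 3 immune markers, CSF1R fell from 1.35 to 0.33 CPM and CD8A rose from 0.29 to 0.87 CPM, both also over the list alone. The median was 0.97 and the mean 0.17, while camera gave a downward direction (adjusted p = 0.958). The immune median was 1.92 without siCTRL replicate 1 and 0.28 without siCTRL replicate 2. The endothelial and immune medians were both -0.58 between the siCTRL libraries. ITGB6 was called with upper-quartile scaling, library totals, the CPM filter, the replicate number as a block or either siCTRL library left out. CD8A was not called with either siMBNL2 library left out, DESeq2 or cyclic loess, and CSF1R without siMBNL2 replicate 1. ACTA2 and COL3A1 also lost their calls under cyclic loess, and ACTA2 shares 30.1% of its exon bases with genes on the other strand.

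**Figure D3:**
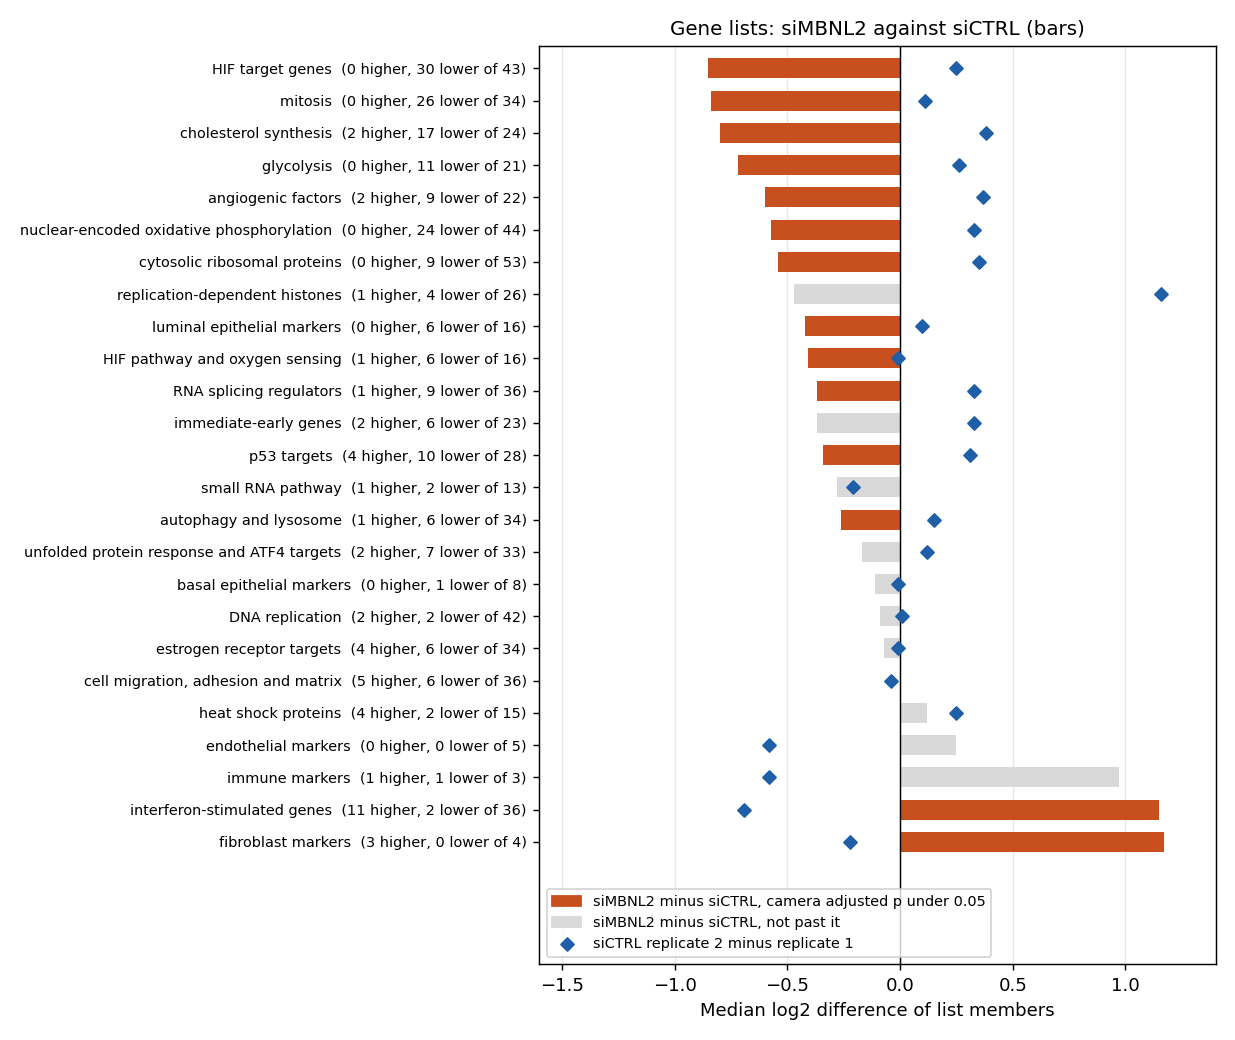
Median log2 difference (siMBNL2 minus siCTRL) of the members of 25 gene lists as bars, orange where the camera adjusted p with a preset correlation was under 0.05, with blue diamonds for the median difference of siCTRL replicate 2 minus replicate 1. HIF target genes (-0.85) and mitosis (-0.84) are the lowest and fibroblast markers (1.17) the highest, and most diamonds lie on the opposite side of 0 from their bar. Among the orange bars, splicing regulators, p53 targets, autophagy and the luminal markers change sign under at least 1 other scaling. Several grey bars do so too, such as DNA replication and the small RNA pathway.

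In all, 14 of the 25 lists passed camera with a preset correlation. Of these, the HIF pathway, splicing, p53, autophagy and luminal lists had medians inside the 95% range of expression-matched random lists, and the other 9 lay outside it. That range can be too narrow for lists whose members vary together. Estimated correlations between members were 0.981 for ribosomal proteins and 0.398 for HIF targets. Lying outside the range therefore does not by itself show that a list responded to the knockdown. With an estimated correlation 0 passed (smallest unadjusted p = 0.0683), and limma's fry gave 0 after adjustment and 5 at an unadjusted p under 0.05, with a smallest adjusted p of 0.0946. The estimated-correlation test had 2 residual degrees of freedom and so little power. The HIF pathway and fibroblast lists lost their calls with estimated correlations of -0.062 and -0.019, below the preset 0.01. For them, correlation between genes was not the reason.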

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

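The fit with cyclic loess was chosen after the data had been seen. MBNL2 fell under every alternative run (log2 fold change -2.89 to -3.30), and neither paralog passed under any. MBNL1 came closest under library totals (0.43, edgeR adjusted p = 0.0579) and cyclic loess (0.33, limma-voom adjusted p = 0.091). In the other alternatives its log2 difference was 0.02 to 0.23. No named gene that was called changed sign, and no list that passed camera in the main fit changed its camera direction where camera was run. Camera was not run with upper-quartile scaling, library totals, DESeq2, limma-voom or cyclic loess. Directions of lists that did not pass were not compared. List medians did turn: under library totals splicing went from -0.37 to 0.02, p53 from -0.34 to 0.04 and autophagy from -0.26 to 0.11, and under cyclic loess splicing went to 0.01 and the luminal markers from -0.42 to 0.20. The cause was not tested.

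Among scalings, upper-quartile factors left 1415 lower genes and library totals 711, of which 1415 and 710 were among the 2425. Cyclic loess gave 1747 higher and 1551 lower genes, of which 1442 and 1272 were shared with the reported ones. At a threshold of 0.01, 0 genes were higher and 1 lower; the stricter threshold itself is the cause. RLE factors, both filters, DESeq2 and limma-voom gave 2104 to 3871 higher and 1854 to 3119 lower genes. Leaving out 1 library at a time gave 672 to 5985 higher and 462 to 5507 lower genes, lowest without siMBNL2 replicate 1 and highest without siCTRL replicate 1. In those fits the lone library is assumed to vary like the other group, and the siMBNL2 pair is the tighter one. The number of lists past the test went from 14 to 0 with an estimated correlation and to 0 with fry, and was 11 to 15 otherwise. Where no cause is named, the cause was not tested.

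The labels do not say whether a replicate number marks a shared batch, and there are only 2 pairs, so a shared batch can be neither assumed nor excluded. With the replicate block, 4110 genes were higher and 3558 lower, 2656 and 2425 of them shared with the reported ones. The deviations of same-numbered libraries correlated at 0.256 across genes.

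Of the 111 called genes among those named by the rule, apart from MBNL2, 111 lost their call at 0.01, 45 without siMBNL2 replicate 1, 31 without siMBNL2 replicate 2, 24 with library totals, 24 with cyclic loess, 13 with upper-quartile scaling, 5 with DESeq2 and 0 without either siCTRL library. For XAF1, the 1 read in the siCTRL libraries left a counting interval of 10.6 to 2430 on the ratio; the effect of depth on other genes was not tested.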

Other observations

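The tests of the HIF target and non-coding patterns, the lists in the next paragraph and the fit with cyclic loess were chosen after the results were seen, while the seed and YGCY tests were set before.

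Further lists were tested, with camera adjusted over these lists alone. PER1, CYP1A1 and ZNF594, already seen among the largest changes, are members of 3 of them. The p-values of those lists are therefore not independent support. Of 18 circadian clock genes, 11 fell and 1 rose (median log2 fold change -0.69, camera adjusted p = 0.000518; adjusted p = 0.297 with an estimated correlation). PER1 (-2.42), NOCT (-1.90) and NR1D1 (-1.74) were lower, whereas PER3 rose (1.29). PER1 stood at 279 and 685 CPM in the siCTRL libraries and 75.3 and 105 CPM in the siMBNL2 libraries, and the median of the list was 0.36 higher in siCTRL replicate 2 than in replicate 1. Of 4 metallothionein genes, 3 fell, including MT1X (-2.09) and MT2A (-1.68), with a median of -1.88 (camera adjusted p = 0.000619; adjusted p = 0.297 with an estimated correlation) and 1.04 between the siCTRL libraries. Of 10 aryl hydrocarbon receptor targets, 4 fell, including CYP1A1 (-2.64) and TIPARP (-2.06), and CYP1B1 was at 0.11 (edgeR adjusted p = 0.712). That list did not pass camera (adjusted p = 0.0846), and its median of -0.16, inside the -0.55 to 0.15 of expression-matched random lists, was 0.01 under upper-quartile scaling, 0.20 under library totals and 0.13 between the siCTRL libraries. Its counts were 2 higher and 3 lower under upper-quartile scaling, 3 and 2 under library totals, and 2 and 2 under cyclic loess. Of 71 mitochondrial ribosomal protein genes, 14 fell and 3 rose (median -0.28, but 0.09 under library totals; camera adjusted p = 0.00204; adjusted p = 0.433 with an estimated correlation), with 0.23 between the siCTRL libraries. The mitochondrial ribosomal counts were 6 higher and 2 lower under library totals, 6 and 39 without siCTRL replicate 1, and 4 and 23 without siCTRL replicate 2. The circadian list had 5 lower genes under library totals (median -0.32) and 6 under cyclic loess. Among 415 genes with a ZNF symbol, most of which encode zinc finger proteins, 143 rose and 25 fell, with a median of 0.53 (camera adjusted p = 2.69e-06; adjusted p = 0.297 with an estimated correlation). Expression-matched random lists had medians of 0.01 to 0.17, and the ZNF median was -0.24 between the siCTRL libraries and positive under every scaling run (0.35 to 0.87). Without siCTRL replicate 1, 245 ZNF genes rose and 72 fell, and without siCTRL replicate 2 the median was 0.34, with 187 higher and 40 lower.

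Among non-coding genes, the types went different ways. Of 1058 lincRNA genes, 271 rose and 28 fell, and of 1216 antisense genes, 348 rose and 29 fell, with medians of 0.70 (95% bootstrap interval 0.64 to 0.79) and 0.78 (0.71 to 0.86). These intervals resample genes, so they hold no spread between libraries. The medians were 0.89 and 0.97 without siCTRL replicate 1 and 0.59 and 0.65 without siCTRL replicate 2, all outside the intervals. In siCTRL replicate 2 the medians were -0.25 and -0.23 relative to replicate 1. Under cyclic loess they shrank to 0.20 and 0.25, with 106 and 142 genes higher. Without siCTRL replicate 1, 495 lincRNA genes rose and 108 fell and 590 antisense genes rose and 100 fell; without siCTRL replicate 2 these counts were 325 and 36, and 410 and 39. Of 654 processed pseudogenes 46 rose and 53 fell (median -0.35, but 0.02 with 58 higher and 18 lower under library totals), and of 268 sense-intronic genes 17 rose and 52 fell (-0.46). Under cyclic loess, 11 processed pseudogenes rose and 85 fell (median -0.91).

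The siCTRL libraries differed along the direction that also separated the groups. Across genes, the difference of siMBNL2 from siCTRL replicate 1 correlated at -0.354 with the difference of siCTRL replicate 2 from replicate 1, where simulated libraries with no effect gave 0.573. The covariance was -0.153, against 0.104 in the simulation, so siCTRL replicate 1 lay between siCTRL replicate 2 and the siMBNL2 libraries. Among 13345 protein-coding genes, the siCTRL difference had Spearman correlations of -0.251 with transcript length and 0.3 with mean expression. The fold change correlated the opposite way, at 0.104 and -0.451, but it includes siCTRL replicate 2, so part of that is built in. Reads without a feature were 20% in siCTRL replicate 2 and 15.3% in siCTRL replicate 1. The cause of the siCTRL difference was not tested. Genes are not independent replicates.

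Off-target activity of the siRNAs through seed matches of the guide strand in 3' UTRs was tested as a source of the changed genes. Genes with a 3' UTR match to the guide's 7-base seed of the MBNL2 siRNA (TTTGTAT, 4515 genes) were lower by a matched median of -0.028 than 8626 genes without one (one-sided permutation p = 0.0004), but 10 of 41 control words of the same composition were as extreme. For the control siRNA's seed site (TGTCACG, 407 genes) the difference was 0.035 (one-sided permutation p = 0.0889), and 41 of 289 control words were as extreme. Both are smaller in size than the 0.05 that was set as the smallest effect of interest, so no broad shift of that size was seen. A median over all genes with a site cannot show repression of a subset of them. The other strand of each siRNA and off-target responses without a seed match were not tested. The density of YGCY words, the motif that MBNL proteins bind, correlated with fold change at -0.018 across 13141 genes, within the -0.028 to 0.022 of other words; binding elsewhere in transcripts stays open.

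The fall of HIF target genes was set against technical trends. Random protein-coding lists of equal expression had medians of -0.47 to -0.19, above the -0.85 of the HIF targets, which argues against a trend with expression level as the whole cause. Against siCTRL replicate 1 alone the median was -0.65, below the -0.40 to -0.19 of random lists that were also matched on the difference between the siCTRL libraries. None of these random lists was matched on transcript length or on the correlation between members, estimated at 0.398 for the HIF targets. Their ranges may therefore be too narrow. HIF1A mRNA fell too (-1.28), which does not by itself separate the explanations. No normoxic library, oxygen measure or cell number is among the data used. Lower oxygen stress or another growth state of the knockdown cultures therefore cannot be told apart from an effect of MBNL2 on HIF transcripts. Whether MBNL2 acts on HIF targets through HIF1A mRNA was not tested.

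The rise of lincRNA and antisense genes was weighed likewise. A smaller share of reads in the 100 most abundant genes would shift all other genes by 0.1 on the log2 scale. The medians of these genes come from fits with TMM factors, which already adjust for such a shift, so this comparison cannot decide the question. Under library totals the lincRNA and antisense medians were 1.05 and 1.13. More unspliced RNA or genomic DNA would raise sense-intronic genes, but their median was -0.46 (95% bootstrap interval over genes, -0.67 to -0.25). That size depended on the scaling (-0.08 under library totals, -0.99 under cyclic loess) and on the controls (-0.19 without siCTRL replicate 2, -0.64 without siCTRL replicate 1). The sense-intronic median was below 0 in each setting for which it was computed. A trend that raises genes with low counts does not account for all of it, since matched protein-coding genes had medians of 0.55 to 0.61 against 0.75 for lincRNA and antisense genes, and sense-intronic genes and processed pseudogenes, with counts as low, had negative medians in the main fit. The remainder may reflect the knockdown, a hypothesis found and tested on the same 4 libraries, and a difference between library preparations was not tested.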
